A study of Drosophila melanogaster with 24 samples.

How the data were processed

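Chromatin immunoprecipitation and sequencing (ChIP-seq) of CLOCK (CLK) and CYCLE (CYC), the paired bHLH-PAS activators of the Drosophila melanogaster circadian clock, was done with an antibody against GFP in heads, testes and ovaries. Per the labels' protocols, 200 heads, or 200 pairs of gonads, were collected for a biological replicate at ZT 10 h, chromatin was sheared to 100 to 500 bp, and 5% of the sample was set aside as input. There were 24 libraries in 12 groups, with 2 GFP libraries and 2 input libraries for each protein and tissue. The fly genotypes, the sex of the flies whose heads were used and any library without a tagged protein were not given in the sources used here.

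The deposited data were 6 peak lists, 1 for each protein and tissue. Per the submitters' processing notes, the build was dm6, and the tools were fastp, Bowtie2, Picard, deepTools, SAMtools, MACS2 and ChIPseeker; versions, settings, the threshold for a peak and the way in which replicates were combined were not given in the sources used here. Each list held 3 columns without a header, which were the chromosome, start and end of each peak, so no height, fold enrichment, p, q or summit was used here. The lists were matched to the tissues by the initials in their names, since each initial fitted only 1 tissue in the labels. The meaning of a further tag shared by all list names was not given, so a filter applied to every list by the authors stays possible. The lowest difference between end and start was 199 bp in every list, and starts may therefore be counted from 0 or from 1; positions are printed as deposited. Read depth was unknown, and 95% intervals are exact Clopper-Pearson intervals that cover the counting of peaks only. Peaks were the units of the tests, except that genes were the units where genes or gene lists were tested. The p-values compare lists and hold no error between replicates.

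Gene positions, symbols and biotypes came from the NCBI RefSeq table of the Release 6 plus ISO1 MT assembly, which dm6 names as well. Its 13922 protein-coding genes on X, 2L, 2R, 3L, 3R and 4 formed the background, and 5 of the symbols in the fixed gene lists were matched through synonyms. The table gave no strand, exons or sequence. The planned window of 1 kb around a transcription start was therefore applied to either end of a gene, peak midpoints took the place of summits, and exons and introns were not told apart. The planned test for the E-box motif needed a genome sequence and was not run. Peak width took the place of the planned fold enrichment and q-value wherever peaks were ranked or filtered, and the lists do not show how closely width follows enrichment.

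Overlap meant at least 1 bp in common. For each of the 15 pairs of lists, the peaks of the shorter list were placed at random 10000 times within their own chromosome at their own widths, and the overlap was tested one-sided; 0.0001 is the smallest p these placements can give. Chromosome ends were set at the last gene or peak, and mappability was not modelled. The share of midpoints near a gene end was tested two-sided against placements of the same kind, with 0.0002 as the smallest p. Shares were compared between lists with Fisher's exact test, the X share was tested against the X share of genes with an exact binomial test, and medians of width were compared with 100000 label permutations, whose smallest p is 1e-05. Shared genes and gene lists were tested with Fisher's exact test over all 13922 genes. There a peak counted for every gene with an end within 1 kb. Neighbouring genes that share a peak are not independent, so these p-values may be too small. Gene length was not allowed for, and where peaks inside genes were counted, longer genes were more likely to hold one. All these tests were two-sided except the overlap test, and p-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Core clock genes were compared between tissues with an exact McNemar test added later.

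The groups, 17 gene lists and the tests, apart from the replaced measures named above, were fixed before the data were examined, as were the alternatives listed first here. Named genes were chosen by a fixed rule, with width as the rank: the 10 genes with the widest peak in a list, all core clock genes, up to 10 genes near peaks of both proteins in a tissue or of 1 protein in 3 tissues, and up to 4 members of each gene list. For these named genes each peak counted only for the gene with the nearest end. The alternatives covered the overlap rule, the window at gene ends, the assignment to genes, the background for X and the removal of regions called in 4 or more lists. As an alternative, assignment to the gene of the nearest end set no limit on distance, while named genes kept to 1 kb. Added after the data were seen were the widest 50%, in place of a stricter q, and the widest 10% of each list, equal list sizes by width, placement at a fixed distance from gene ends, assignment to gene bodies, removal of the histone cluster, contigs and mitochondrial genome, and, for X, removal of regions called in 4 or more lists.

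Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The overlap test was tested on simulated data with the sizes of the CLK and CYC lists of testis, 1583 and 2491 peaks. Of 100 unrelated pairs, 3 passed 0.05, and with 100 planted shared peaks all 100 pairs passed, with an excess of 98.5 ± 3.91 (SD over the simulated pairs). The unrelated lists were placed uniformly, as in the test itself, so the simulation checks the computation only. It does not give the rate of false calls for real peaks, which crowd near gene ends. bedtools 2.31.1 gave the same 226 overlapping peaks for that pair.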

Results

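The series asked where CLK and CYC are found on chromatin in head and in the reproductive organs. CLK and CYC act as a pair in the fly clock, where they activate period (per), timeless (tim), vrille (vri) and Par-domain protein 1 (Pdp1). The head lists held 1016 CLK peaks and 394 CYC peaks. The testis lists held 2491 and 1583, and the ovary lists 351 and 1975. Median widths lay between 272 bp for CYC in testis and 312 bp for CYC in ovary. No head peak lay in the histone gene cluster (2L, 21416953 to 21541681, 111 histone genes in the annotation), while 89 CLK and 41 CYC peaks of testis and 8 CLK and 113 CYC peaks of ovary lay in it or within 1 kb. Each list drew on 2 GFP and 2 input libraries and none was given per replicate, so numbers of peaks were not tested and read depth was unknown.

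In head, CLK and CYC were called together at vri, tim, per and Pdp1. All 6 CLK peaks in or within 1 kb of vri, which encodes a bZIP repressor of Clk, met a CYC peak, as did both CLK peaks of tim, 2 of 3 at per and 4 of 9 at Pdp1. None of the 3 CLK peaks of Clk, the 2 of sgg or the 1 of jet met a CYC peak, and dco had CYC peaks only. The widest peak of each head list lay inside vri, at 2L 5302214 to 5304234 for CLK (2020 bp) and at 5302211 to 5304868 for CYC (2657 bp). At tim the widest CLK peak was at 2L 3507123 to 3508243 (1120 bp), and at per it was at X 2684540 to 2685615 (1075 bp), each reaching past an end of the gene. Over the whole lists, 116 of 394 CYC peaks met a CLK peak (29.4%, 95% interval 25.0 to 34.2%), against 1.98 at random placement. This was a 58.6-fold excess (one-sided permutation test, adjusted p = 0.000188, from the smallest p the placements can give). The excess ranged from 21.3 to 139-fold over 8 alternative settings.

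Beyond the clock genes, the head genes with the widest peaks of both proteins near an end were sni, H15, sNPF-R, lace, CG34220, Brr2 and CG13476, whose peaks met except at sni. sNPF-R encodes the receptor of short neuropeptide F, lace a subunit of serine palmitoyltransferase and H15 a T-box transcription factor. At sNPF-R the CLK peak (3L 20088764 to 20089279, 515 bp) and the CYC peak (3L 20088865 to 20089263, 398 bp) lay within 57 bp, by their midpoints, of the same end. At lace the CYC peak was the wider, at 680 bp against 469 bp for CLK. Other wide peaks were called in head for 1 protein, as at Bx (X 18515359 to 18516260) and disco (X 16216920 to 16217678) for CLK and at Cyp28d2 (2L 5207987 to 5208956) for CYC. With a peak near either end, 978 genes were counted for CLK and 471 for CYC, and 123 were shared where 33.1 were expected from independent lists (3.72-fold, Fisher's exact test, adjusted p = 1.41e-38). These genes came from 647 CLK and 279 CYC peaks, so neighbours that share a peak were not independent.

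In testis, 226 of 1583 CYC peaks met a CLK peak (14.3%, 12.6 to 16.1%), against 28.4 at random placement (7.95-fold, one-sided permutation test, adjusted p = 0.000188, again from the smallest p). The widest CYC peak of testis lay inside Clk, at 3L 7764179 to 7767132 (2953 bp), and met 2 of the 4 CLK peaks of that gene. The next widest were at the end of Act5C (X 5898333 to 5900970, 2637 bp), which encodes a cytoplasmic actin, and in white (w), an eye pigment transporter gene (X 2791371 to 2793169, 1798 bp). The peak at w overlapped the annotated gene kirre as well. These 3 sites were the widest of the list and were looked up after their values were seen. The fly genotypes were not given in the sources used here, so peaks at w, Clk and Act5C were not checked against construct sequence. Genes near wide peaks of both proteins included CG7465, CG31872, w, CG9988, lectin-24Db and the glycosyltransferase gene Ugt303B3. At CG31872 the peaks spanned 2L 10642435 to 10643182 for CLK (747 bp) and 10642397 to 10643175 for CYC (778 bp). The proteins shared 244 genes where 103 were expected (2.37-fold, Fisher's exact test, adjusted p = 2.89e-40), and 173 where 88.8 were expected without the histone genes (1.95-fold). Over 7 alternative settings shared genes ranged from 1.48 to 3.96-fold. The overlap of peaks ranged from 4.16 to 16.8-fold over 8 alternative settings.

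In ovary, 110 of 351 CLK peaks met a CYC peak (31.3%, 26.5 to 36.5%), against 16.2 at random placement (6.79-fold, one-sided permutation test, adjusted p = 0.000188, from the smallest p). Histone genes led the genes with both proteins. At His1:CG33813 the CLK peak was at 2L 21450362 to 21450831 and the CYC peak at 21450309 to 21451778. By the nearest-end rule for named genes, 26 genes had peaks of both proteins. Among the 10 named by width, those outside the histone cluster were Ser6, Hsp60D, a gene of the mitochondrial chaperone family, TTLL1A and CG32713. The peaks at Hsp60D did not meet, with CLK at one end (2L 13447025 to 13447391) and CYC at the other (13449875 to 13450661). At CG32713 the CLK peak (X 8456859 to 8457068) lay within the CYC peak (X 8456581 to 8457245). Shared genes numbered 40 where 9.39 were expected (4.26-fold, Fisher's exact test, adjusted p = 2.8e-15), and 25 where 7.44 were expected without the histone genes (3.36-fold). Over 7 alternative settings shared genes ranged from 2.63 to 6.78-fold. The overlap of peaks ranged from 4.59 to 38.0-fold over 8 alternative settings, and it was 19.0-fold without the histone cluster, contigs and mitochondrial genome.

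**Figure D1:**
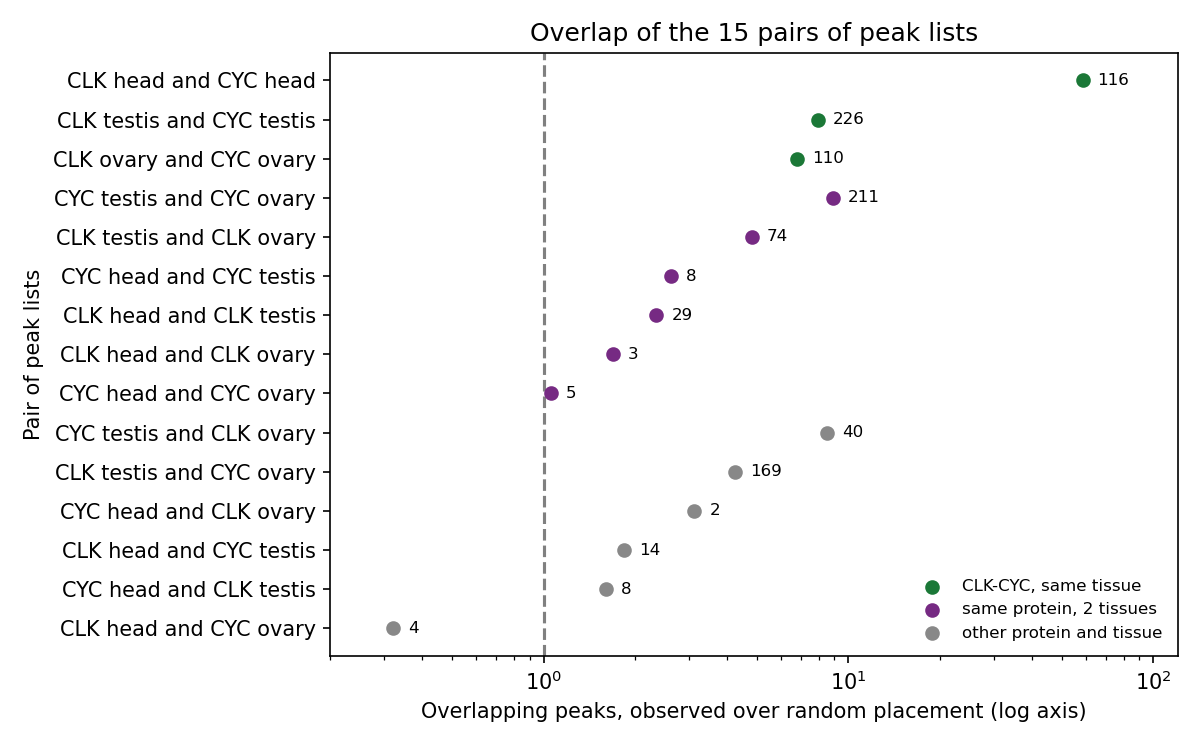
Overlapping peaks of the shorter list over the mean of 10000 random placements (log axis), for the 15 pairs of lists; the number beside each point is the count of overlapping peaks and the dashed line marks 1. The head pair of CLK and CYC stands at 58.6, and the pairs of gonad lists lie between 4.23 and 8.89. The highest fold possible falls as the number expected rises, so folds do not rank the pairs. By share of the shorter list, CLK and CYC met in 29.4% in head, 14.3% in testis and 31.3% in ovary.

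Head and gonads had few sites in common for either protein. Of the 1016 CLK head peaks, 29 met a CLK testis peak, 2.34-fold over random (permutation test, adjusted p = 0.000188), and of the 351 CLK ovary peaks, 3 met a head peak (1.68-fold, permutation test, adjusted p = 0.312). Of the 394 CYC head peaks, 8 met a CYC testis peak (2.62-fold, permutation test, adjusted p = 0.0227) and 5 a CYC ovary peak (1.06-fold, permutation test, adjusted p = 0.547). Testis and ovary had more in common, with 74 of 351 CLK ovary peaks meeting CLK testis peaks (4.82-fold) and 211 of 1583 CYC testis peaks meeting CYC ovary peaks (8.89-fold, permutation test, both adjusted p = 0.000188). Over 8 alternative settings these ranged from 3.22 to 28.1-fold for CLK and from 5.59 to 22.0-fold for CYC. The excess of both head and testis pairs no longer passed when placements kept the distance to gene ends, at 1.20-fold for CLK and 1.72-fold for CYC. With lists of equal size both passed, at 7.24-fold from 7 peaks for CLK and 6.61-fold from 5 peaks for CYC. The CYC pair did not pass with reciprocal overlap of 50% (2.76-fold), midpoints within 200 bp (2.59-fold), the widest 50% (3.09-fold) or without regions called in 4 or more lists (1.98-fold). Head and ovary fell below random with that placement, at 0.929-fold for CLK and 0.637-fold for CYC, and the CYC pair did so in 4 further settings.

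With each peak counted for the gene of the nearest end within 1 kb, Prosbeta5R2, a paralogue of a proteasome subunit gene, was the only gene given a CLK peak in all 3 tissues, and no gene was given a CYC peak in all 3. Its CLK peaks were at 2L 17990810 to 17991232 in head, 17990565 to 17991386 in testis and 17989850 to 17990266 in ovary, so the ovary peak lay apart from the others. At the level of genes, CLK of head and CLK of testis shared 121 where 114 were expected (1.06-fold, Fisher's exact test, adjusted p = 0.502). That value rose to 1.54-fold with the gene of the nearest end, here at any distance. With peaks inside genes included it rose to 1.45-fold, and both values passed the threshold. Under both rules every pair of a head and a gonad list rose, so the rise was not particular to this pair. For CLK of head and testis the value was below 1 at 500 bp (0.913-fold) and in the widest 50% of peaks (0.716-fold). CLK of testis and ovary shared 44 genes (3.08-fold, Fisher's exact test, adjusted p = 4.78e-12), and CYC of testis and ovary shared 159 (2.35-fold, adjusted p = 8.44e-25). Without histone genes the latter was 85 (1.52-fold). Over 7 alternative settings these pairs ranged from 1.42 to 5.17-fold and from 1.52 to 3.84-fold.

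The share of the shorter list that met the partner protein was 15.2 points higher in head than in testis (Fisher's exact test, adjusted p = 2.67e-11) and differed by -17.1 points for testis minus ovary (adjusted p = 2.77e-12). Both differences passed in all 6 alternative settings, from 6.27 points, with lists of equal size, to 17.6 points for head minus testis and from -20.6 to -5.24 points, with reciprocal overlap, for testis minus ovary. The head value, at 116 of 394, and the ovary value, at 110 of 351, differed by -1.90 points for head minus ovary (Fisher's exact test, adjusted p = 0.577). With reciprocal overlap of 50% this last difference became 9.33 points, and with midpoints within 200 bp it became 9.46, both past the threshold. It was 3.46 points without regions called in 4 or more lists and 3.52 without the histone cluster, contigs and mitochondrial genome, which did not pass, and -9.66 in the widest 50%, which did. The shorter list was that of CYC in head and testis and that of CLK in ovary, so the shares do not refer to the same protein.

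Within 1 kb, head peaks lay near gene ends more often than gonad peaks did. Midpoints within 1 kb of an end of a protein-coding gene made up 63.7% of CLK and 70.8% of CYC peaks in head, 46.9% and 40.8% in testis, and 30.4% and 41.1% in ovary. Random placement gave 24.4 to 25.0%. Every list exceeded it (two-sided permutation test, adjusted p = 0.00024 for 5 lists, from the smallest p the placements can give), with CLK in ovary the closest at 1.25-fold (adjusted p = 0.0136). That value no longer passed with a window of 500 bp (1.15-fold), with the widest 50% of peaks (1.23-fold) or without the histone cluster, contigs and mitochondrial genome (1.20-fold). CLK head exceeded CLK testis by 16.7 points and CYC head exceeded CYC testis by 30.0 points (Fisher's exact test, adjusted p = 4.79e-19 and 3.01e-26). With a window of 3 kb the CLK difference turned to -2.62 points and did not pass, and that of CYC was 7.41 points.

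The core clock list had 16 members, and those near head peaks were Clk, Pdp1, jet, per, tim and vri for CLK and dco, per, tim and vri for CYC. jet encodes an F-box protein and dco the kinase Doubletime. These 6 and 4 members were 5.34 and 7.39 times the share of all genes (Fisher's exact test, adjusted p = 0.0105 and 0.0217). The CYC call was lost with windows of 500 bp (5.02-fold) and 3 kb (4.16-fold). In the gonads, only cyc was near a CLK testis peak (3L 19814005 to 19814488), only Clk near a CLK ovary peak (3L 7776430 to 7776651) and only sgg, a kinase gene, near a CYC ovary peak (X 2678997 to 2679412), with none for CYC in testis. Whether the tissues differed was left undecided, since with so few genes the exact McNemar test could not give an adjusted p below 0.0625 (lowest adjusted p = 0.25). With peaks inside genes included, CYC of ovary had 6 members, CkIIalpha, CkIIbeta, Clk, Pdp1, per and sgg, against 5 for CYC of head, and passed at 3.37-fold. It passed also with a window of 3 kb (2.82-fold) and with the gene of the nearest end (4.38-fold). A long gene is more likely to hold a peak inside it. Since gene length was not allowed for, calls gained with peaks inside genes, in this and the other gene lists, may reflect long members. Peaks inside genes were more widespread, and Clk held peaks of CLK in all 3 tissues. By peak midpoints, no list had a peak in or within 1 kb of cry, nmo, slmb or cwo. With a window of 3 kb, and with the gene of the nearest end, cwo was given a CLK head peak.

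**Figure D2:**
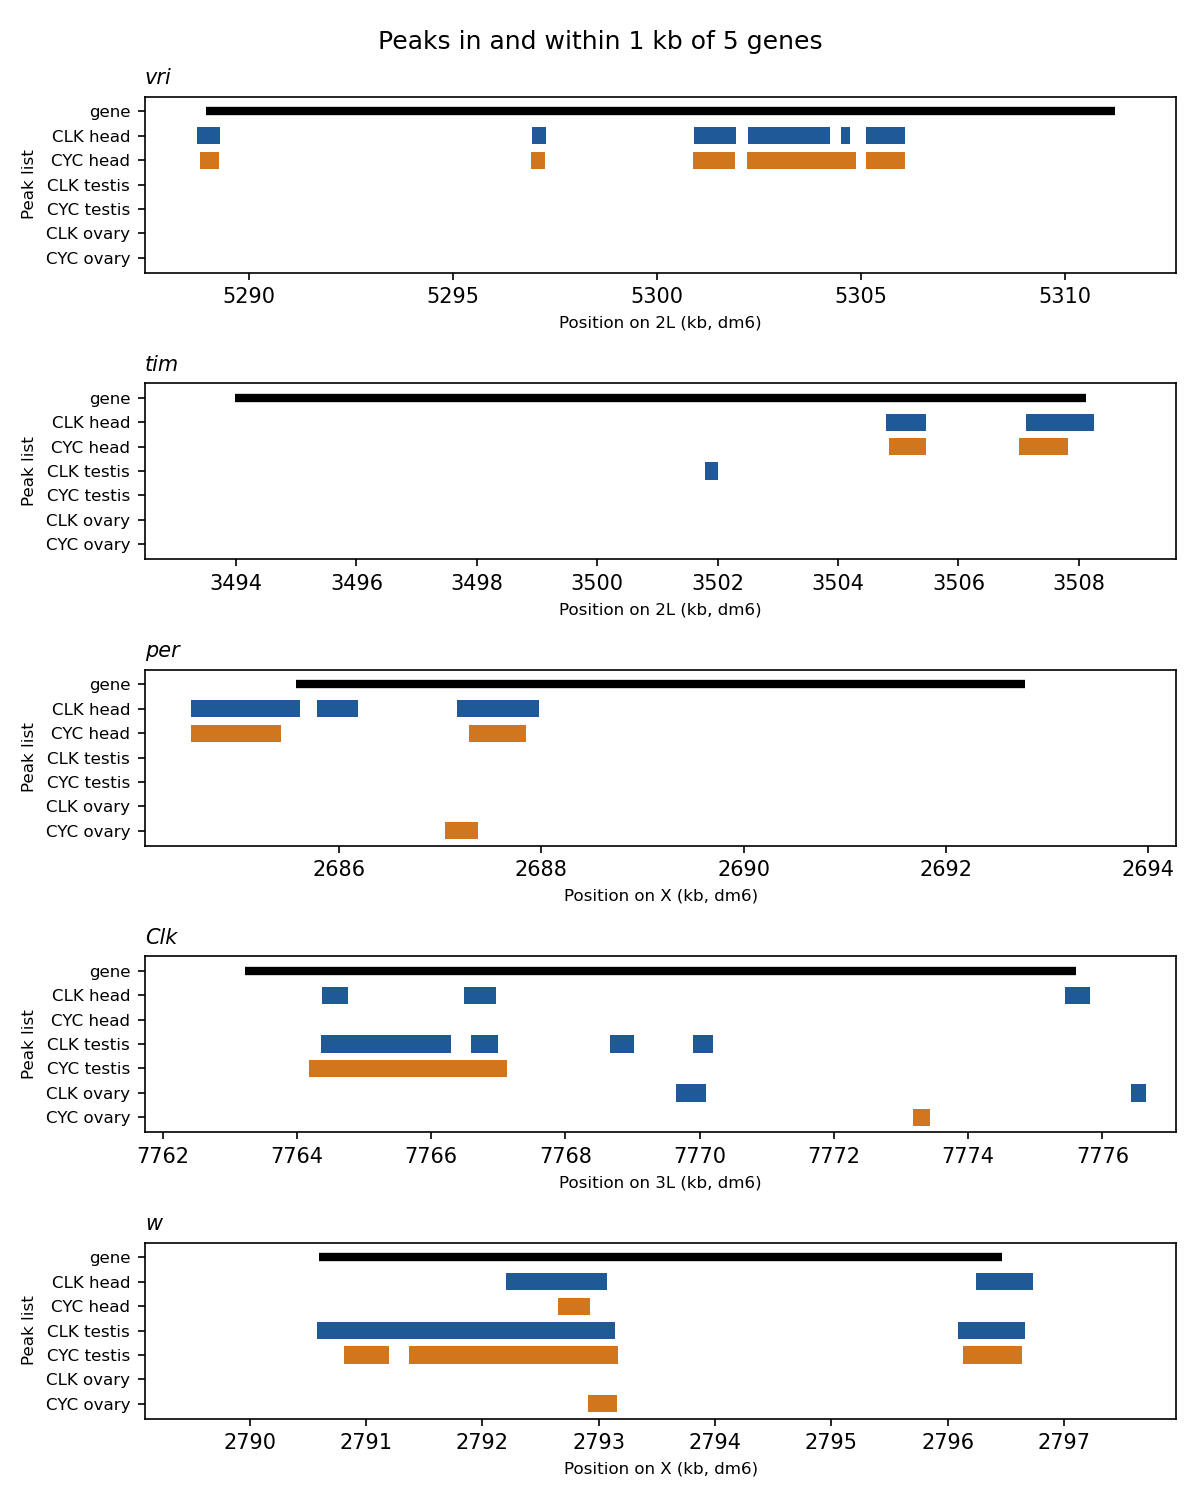
Peaks of the 6 lists (blue for CLK, orange for CYC) in and within 1 kb of vri, tim, per, Clk and w, along the chromosome in kb (dm6), with the annotated gene as a black bar. CLK and CYC head peaks lie over each other at vri, tim and per, while at Clk the CYC peak of 2953 bp is from testis.

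Among phototransduction genes, 6 of 19 were near CYC peaks of testis, namely the arrestin genes Arr1 and Arr2, the opsin genes Rh2 and Rh6 and the channel genes trp and trpl (5.00-fold, Fisher's exact test, adjusted p = 0.0142). This call was lost with a window of 500 bp (5.45-fold) and with the gene of the nearest end (2.83-fold). CLK of head was near 5 members, among them Rh5, ninaC and trp (Fisher's exact test, adjusted p = 0.0876). With peaks inside genes included, 7 members for CLK head (4.06-fold) and 9 for CLK testis (2.66-fold) passed, as both did with a window of 3 kb (3.00 and 2.33-fold). None of the 92 ribosomal protein genes was near a CYC ovary peak (Fisher's exact test, adjusted p = 0.0174), against 7.69% of all genes, and this call was lost with windows of 500 bp and with the widest 50% of peaks, where the count was again 0 of 92 and fewer genes were near peaks, and with 3 kb, at 6 of 92 (0.420-fold). The 115 histone genes were near peaks in 108 cases for CLK and 74 for CYC in testis, and in 15 and 111 cases in ovary (Fisher's exact test, highest adjusted p = 1.68e-12). Of these genes 111 lie in 1 cluster, so they are not independent and the p-values overstate the evidence. The cluster held 89 CLK and 41 CYC peaks of testis and 8 CLK peaks of ovary, so 1 peak counted for several genes. The CLK ovary call was lost with the gene of the nearest end, at 7 genes (3.22-fold). These gene copies are nearly identical, so reads cannot be placed among them with certainty.

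The other 13 lists passed in no tissue with ends within 1 kb. With peaks inside genes included, muscle genes passed for CYC ovary (4.49-fold), testis meiotic arrest genes for CYC head (6.05-fold) and germline stem cell genes for CLK ovary (7.88-fold), and with a window of 3 kb eggshell and yolk genes passed for CYC ovary (2.86-fold). Of 21 clock output and clock neuron genes, at most 2 were near peaks of 1 list, as ITP and Mid1 in CLK head, and the highest fold was in CLK ovary, with CCHa1 (5.43-fold). Of 15 neuronal and synaptic genes, CLK head had Gad1 and futsch (1.90-fold) and CYC head had brp, a gene of the presynaptic active zone (1.97-fold). Gonad counts were alike, with Gad1 and Rdl for CLK testis (1.14-fold), Syt1 for CYC testis (1.05-fold) and Syn and Syt1 for CYC ovary (1.73-fold). Of 16 testis meiotic arrest genes, CLK testis had kmg and twe and CYC testis had Rbp4, while the highest fold over all genes was in CYC head, with mia and topi (3.69-fold). Of 22 spermiogenesis genes, CLK testis had Mst84Dd and Mst98Ca and CYC testis had Mst98Ca and S-Lap4, and the highest fold was again in CYC head, with Mst77F and fzo (2.69-fold). The germline stem cell list, also with 22 members, had hh for CLK testis (0.388-fold), Socs36E and otu for CYC ovary (1.18-fold), bgcn and dpp for CLK head (1.29-fold) and, with the highest fold, bgcn and gbb for CYC testis (1.44-fold). Of 18 piRNA pathway genes, aub and Panx were near CLK testis peaks and AGO3 near a CYC ovary peak, while the highest fold was in CLK head, with armi and cuff (1.58-fold). Of 18 eggshell and yolk genes, Cp36, Yp3 and psd were near CYC ovary peaks, and of 15 oocyte axis genes, BicC and BicD were (1.73-fold), beside exu for CYC head (1.97-fold). Of 12 seminal fluid protein genes, Acp98AB was near a CLK testis peak. The largest counts in the remaining lists were 4 of 17 heat shock genes for CYC ovary (3.06-fold, beside 3.48-fold from 2 genes for CYC head), 3 of 14 antimicrobial peptide genes for CLK testis, 4 of 26 ecdysone and juvenile hormone genes for CLK testis and 3 of 12 muscle genes for CYC ovary.

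X carried few testis peaks and many ovary peaks. It held 15.8% of protein-coding genes. In testis it held 34 of 2426 CLK peaks (1.40%, 0.972 to 1.95%) and 56 of 1525 CYC peaks (3.67%, 2.79 to 4.74%; exact binomial test, adjusted p = 9.02e-129 and 2.44e-51). In ovary it held 107 of 332 CLK peaks (32.2%, 27.2 to 37.5%) and 406 of 1936 CYC peaks (21.0%, 19.2 to 22.9%), with exact binomial adjusted p = 2.57e-13 and 2.45e-09. In head the shares were 14.5% for CLK (exact binomial test, adjusted p = 0.263) and 10.4% for CYC (adjusted p = 0.00345). Near gene ends the testis shares were 0.439% for CLK and 1.77% for CYC, and away from them 2.25% and 4.98%. In the widest 10% of peaks, with 28 to 186 peaks in these lists, CYC testis (0.588 times the share of genes), CYC head (0.325), CLK ovary (1.81) and CYC ovary (1.16) no longer passed, beside 0.233, 0.659, 2.04 and 1.33 over all peaks. CLK testis still passed, at 0.245 beside 0.0888. With arm lengths as background CLK head passed as well, at 0.821 times the background.

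**Figure D3:**
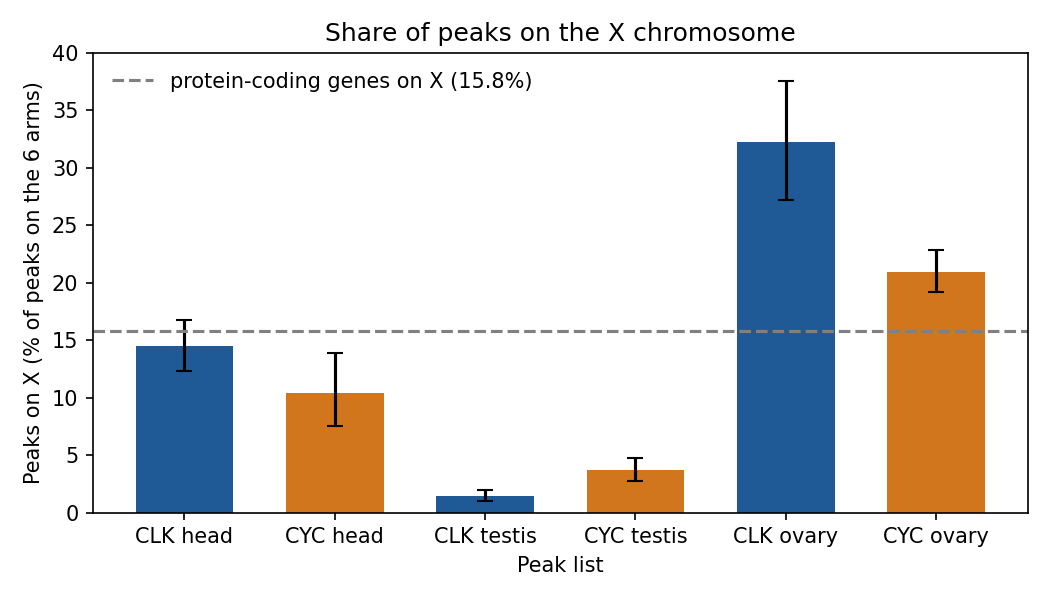
Share of peaks on X in each list, as a percentage of the peaks on the 6 arms, with exact 95% intervals as error bars (blue for CLK, orange for CYC); the dashed line is the share of protein-coding genes on X, 15.8%. The testis lists stand at 1.40% and 3.67% and the ovary lists at 32.2% and 21.0%.

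Peaks that met the partner protein were wider than the rest of their list in 5 of 6 lists. The difference of medians was 37 bp for CLK and 34 bp for CYC in head, 64.5 bp for CLK in testis, and 73 bp for CLK and 265 bp for CYC in ovary (permutation test, adjusted p from 3e-05, resting on the smallest p the permutations can give, to 0.00756). In CYC testis it was 11.5 bp (permutation test, adjusted p = 0.128), and 24 bp, past the threshold, without the histone cluster, contigs and mitochondrial genome. Wider peaks overlap more often by chance, and with midpoints within 200 bp as the rule the CLK ovary difference was 14 bp and did not pass, while that of CYC ovary was 124 bp and that of CLK testis 37.5 bp. With reciprocal overlap of 50% CYC head (23 bp) and CLK ovary (37.5 bp) did not pass, and CLK head rose to 66 bp.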

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

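The tests of technical explanations given here were chosen after the results were seen, while the comparisons between tissues were planned. All values compare single lists and hold no error between replicates.

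The share of peaks that met the partner protein differed between tissues by 15.2 points for head minus testis and by -17.1 points for testis minus ovary. The share of peaks near a gene end differed by 16.7 points for CLK head minus CLK testis, by 33.3 for CLK head minus CLK ovary and by 16.5 for CLK testis minus CLK ovary. For CYC it differed by 30.0 points for head minus testis and by 29.7 for head minus ovary. With a window of 3 kb the values of CLK were -2.62, 18.5 and 21.1 points in the same order, and those of CYC 7.41 and 13.7. On X, the difference was 13.1 points for CLK head minus CLK testis, -17.8 for CLK head minus CLK ovary and -30.8 for CLK testis minus CLK ovary. For CYC on X it was 6.73 points for head minus testis, -10.6 for head minus ovary and -17.3 for testis minus ovary. In the widest 10% of peaks CYC head minus CYC testis turned to -4.14, and this value, CLK head minus CLK ovary (-14.7) and CYC head minus CYC ovary (-13.2) did not pass.

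The scarcity of X peaks in testis was weighed against a masked part of X and against the single X copy of males, which may have removed calls near the caller's threshold. Masking of whole stretches of 2 Mb is argued against by the spread of the testis peaks, which lay in 12 of 12 windows of 2 Mb. Any testis peak fills a window, so masking of shorter parts within the windows stays open. Threshold loss remains open: the X share in the widest 10% of peaks was 3.86% for CLK (upper bound 7.21%) and 9.27% for CYC (upper bound 15.1%), above the 1.14% and 3.06% of the other peaks (Fisher's exact test, adjusted p = 0.00365 and 0.00139) but below the 15.8% of genes. The values in the widest 10% rest on 9 of 233 peaks for CLK and 14 of 151 for CYC. Among these were peaks at w (width ranks 8 and 123 for CLK, 3 and 90 for CYC) and yellow (y, ranks 184 and 17). For CYC the peak at Act5C (rank 2) was among them as well. None of these was checked against construct sequence, and the rise with width was not tested without them. With each list cut at its median width, 16 of 1211 wider CLK peaks lay on X (1.32%). This was no rise over the 1.40% of all CLK peaks. For CYC it was 36 of 763 (4.72%), beside 3.67% of all CYC peaks. Width as a stand-in for strength and the missing read depth keep these values from deciding. Y, also a single copy in males, held 10.6 peaks per Mb in each testis list, beside 1.44 for CLK and 2.38 for CYC on X. Chromosome 4, an autosome, held 3.15 for CLK and 4.72 for CYC, below the 19.8 and 12.5 of 3L. Repeated sequence on Y and the differing gene content of these chromosomes keep this comparison from deciding as well. A difference of tissue, such as the state of X chromatin in male germ cells, is an untested hypothesis that stays open beside threshold loss.

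The coincidence of CLK and CYC was weighed against reads of the histone cluster, contigs and mitochondrial genome and against places that any GFP immunoprecipitation might recover. These 3 classes as the whole cause are argued against, since without them the overlap was 9.50-fold in testis and 19.0-fold in ovary. Regions called in 4 or more lists, among them 8 near the end of X and sites in Muc26B and Muc30E, were removed separately. The overlap was then 8.55-fold in testis and 14.4-fold in ovary, both past the threshold, which argues against these regions as the whole cause. Repeated sequence called in fewer lists, such as at Ste and other mucin genes, the end of X and Y, stays open. For head, background common to all tissues is argued against, because without the 3 classes the highest overlap of a head list with the other protein in another tissue was 3.15-fold, from 2 peaks, beside 59.3-fold for the head pair. Over 9 settings it was at most 11.3% of the head pair's value (8.36 beside 74.3-fold, lists of equal size). Folds depend on the number expected, so shares of the shorter list are given as well. With all peaks the head pair met in 29.4%, and head lists met the other protein in another tissue in 0.394 to 2.03%. Background at chromatin open only in head was not tested and stays open. For testis and ovary both kinds stay open, since CYC testis and CLK ovary, which differ in protein and tissue, overlapped 14.9-fold while CLK testis and CYC ovary overlapped 2.81-fold, values that sites bound in both gonads would give as well, and libraries without a tagged protein were not used here.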

How the results depend on the processing

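No paired analysis was possible because the files hold 1 list per protein and tissue and none per replicate, and no replicate could be left out. The E-box alternatives were not run, and merging overlapping peaks changed nothing, as no list had any. The widest 10% and 50%, equal sizes, distance-keeping placement, gene-body assignment and removal of multi-copy regions (here the histone cluster, contigs and mitochondrial genome) were chosen after seeing the data. Of 459 alternative values, 349 kept direction and side of the threshold, 38 lost the call, 29 gained one and 43 changed direction. Of 102 gene-list tests, the 18 that passed in any setting are counted here, and the other 84 passed in none. The cause was not tested, and the widest 10% and 50% hold fewer peaks. Depth is unknown, so peaks missing from short lists cannot be called absent.

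For overlap over random, CYC head and testis lost its call with reciprocal overlap (2.76), midpoints within 200 bp (2.59), distance-keeping placement (1.72), without regions in 4 or more lists (1.98) and in the widest 50% (3.09). CLK head and testis lost it with distance-keeping placement (1.20), while equal sizes gave 7.24 for CLK and 6.61 for CYC, both past the threshold. CLK head and CYC testis (1.84) lost its call with reciprocal overlap (1.45), midpoints (1.66), distance-keeping placement (1.17) and without regions in 4 or more lists (1.60), and kept it at equal sizes (8.36), where CYC head and CLK testis gained one (4.56). CYC head and ovary, without a call, fell below 1 with midpoints (0.911), distance-keeping placement (0.637), without regions in 4 or more lists (0.857), in the widest 50% (0.598) and at equal sizes (0). So did CLK head and ovary (0.929) and CYC head and CLK testis (0.859) with distance-keeping placement. The shared share for head minus ovary turned to 9.33 points with reciprocal overlap and 9.46 with midpoints, both past the threshold, and to 3.46 without regions in 4 or more lists and 3.52 without multi-copy regions, neither past it. It was -9.66 and past the threshold in the widest 50%.

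The gene-end share of CLK ovary lost its call at 500 bp (1.15), in the widest 50% (1.23) and without multi-copy regions (1.20). CLK head minus CLK testis turned to -2.62 points at 3 kb, without a call. CYC testis minus CYC ovary was past the threshold at 500 bp (-6.88 points) and, turned, at 3 kb (6.26), and turned without a call in the widest 50% (2.77) and without multi-copy regions (1.52). For X over background, CLK head gained a call with arm lengths (0.821), CYC ovary lost it in the widest 50% (1.14), and in the widest 10% CYC head (0.325), CYC testis (0.588), CLK ovary (1.81) and CYC ovary (1.16) lost theirs. Of the differences on X, the widest 10% ended the calls of CLK head minus CLK ovary (-14.7 points) and CYC head minus CYC ovary (-13.2) and turned CYC head minus CYC testis to -4.14.

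For shared genes over chance with the gene of the nearest end, CLK head gained calls with CLK testis (1.54) and CLK ovary (1.91), and turned upward, past the threshold, with CYC testis (1.31) and CYC ovary (1.49), as did CYC head with CLK testis (1.45). CYC head turned upward without a call with CYC testis (1.19), CLK ovary (1.29) and CYC ovary (1.27). With gene bodies these 8 pairs, in that order, gave 1.45, 2.24, 1.29, 1.49, 1.30, 1.23, 1.31 and 1.33, the last now past the threshold. At 3 kb, CLK head and CLK testis (1.09), CYC head and CLK ovary (0.417) and CYC head and CYC ovary (0.793) gained calls, CLK head with CYC testis (0.946) and CLK testis with CYC ovary (1.02) lost theirs, and CLK head with CLK ovary (0.945) and CYC head with CLK testis (1.03) turned without a call. CLK head and CLK testis turned at 500 bp (0.913) and in the widest 50% (0.716), and CLK head and CLK ovary at 500 bp (0.992), none with a call. In the main setting CLK head and CYC testis shared 41 genes where 61.8 were expected (0.663-fold, Fisher's exact test, adjusted p = 0.00628). This was below chance, while the peaks of the pair overlapped above random (1.84-fold). CLK head and CYC testis lost its call also at 500 bp (0.551), in the widest 50% (0.742) and without multi-copy regions (0.719). CYC testis and CLK ovary lost it at 500 bp (2.83) and without multi-copy regions (1.92), where CLK testis and CYC ovary turned to 0.983. CYC head and CYC testis gained a call without regions in 4 or more lists (0.611).

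Among gene lists, the core clock in CYC head lost its call at 500 bp (5.02) and 3 kb (4.16), phototransduction in CYC testis at 500 bp (5.45) and with the nearest end (2.83), ribosomal proteins in CYC ovary at 3 kb (0.420), at 500 bp and in the widest 50% (0 in both), and histones in CLK ovary with the nearest end (3.22). Calls gained at 3 kb, with the nearest end and with gene bodies were those of the core clock in CYC ovary (2.82, 4.38 and 3.37, up from 0.812), phototransduction in CLK head (3.00, 4.80 and 4.06), muscle in CYC ovary (3.22, 5.00 and 4.49) and, downward, ribosomal proteins in CYC testis (0.337, 0.117 and 0.107). The core clock in CYC ovary turned upward without a call at 500 bp (1.30) and in the widest 50% (1.85). Germline stem cell genes in CLK ovary turned from 0 to 7.94 at 3 kb and 7.88 with gene bodies, past the threshold, and to 7.22 with the nearest end, not past it. Phototransduction in CLK testis (2.33 and 2.66) and, downward, histones in CLK head (0.0708 and 0.0959) gained calls at 3 kb and with gene bodies. Eggshell and yolk genes in CYC ovary (2.86) and, at 0, histones in CYC head gained them at 3 kb, and testis meiotic arrest genes in CYC head with gene bodies (6.05), where the widest 50% gave 0. For width, CLK ovary lost its call with reciprocal overlap (37.5 bp) and midpoints (14 bp) and CYC head with reciprocal overlap (23 bp), while CYC testis gained one without multi-copy regions (24 bp).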

Other observations

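The tests in this part were chosen after the results were seen.

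Chromosome 4, the small and largely heterochromatic autosome, held 78 of 1936 CYC ovary peaks (4.03%, 3.20 to 5.00%), 7.01 times its 0.575% of protein-coding genes (exact binomial test, adjusted p = 1.16e-38). For CLK in ovary it held 7 of 332 (3.67-fold, exact binomial test, adjusted p = 0.00848), for CLK in testis 4 of 2426 (0.287-fold, adjusted p = 0.00848), and the other 3 lists did not pass. By length chromosome 4 makes up 0.952% of the arms. The shares were not tested against length, by which the ovary excess would be smaller. Among 76 families of genes with a common symbol stem and at least 10 members, 3 of 456 tests passed. Stellate (Ste) genes, a repeated family on X, were near CYC ovary peaks in 10 of 13 cases (10.0-fold, Fisher's exact test, adjusted p = 7.34e-07), and their copies are so alike that reads cannot be placed with certainty. The alkaline phosphatase (Alp) genes were near CLK testis peaks in 7 of 12 cases (4.99-fold, Fisher's exact test, adjusted p = 0.0268). Of the mucin (Muc) genes, whose coding sequences carry repeats, Muc26B, Muc4B and Muc96D were near CLK ovary peaks, 3 of 13 (26.3-fold, Fisher's exact test, adjusted p = 0.0268).

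Of 6922 merged regions, 6257 were called in 1 list and 21 in 4 or more. Of these 21, 19 were called in exactly the 4 gonad lists, among them 8 regions near the end of X, 6 on contigs or the mitochondrial genome, and sites in Muc26B (2L 6152525 to 6152976) and Muc30E (2L 9900897 to 9901306). The 2 that included head were CG7465 (3L 4480618 to 4481488), called for both proteins in head and testis, and w. Peaks on Y numbered 39 for each protein in testis, 16 for CYC in ovary and 0 in the other lists. Females carry no Y, and no explanation for the Y peaks of the ovary list was tested.

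A region in w (X 2790577 to 2793169) was the only one called in 5 lists, all but CLK ovary. The annotated gene w lies at X 2790599 to 2796466, and kirre and CG32795 are annotated at the same region. Peaks of all lists at w formed 2 blocks, that region and X 2796089 to 2796733, with 2920 bp between them free of any peak. One candidate explanation is w sequence carried by a transgene, since the mini-white marker of many fly constructs lacks most of the first intron. The gap in CLK head, CLK testis and CYC testis is what such a marker would leave, but CYC head and CYC ovary had peaks in the first block only, CLK ovary had none, the annotation used gives no introns and the genotypes were not given in the sources used here, so a marker and binding at w cannot be told apart. A test would be the read depth of the input libraries over w. Peaks also met inside y, at X 359877 to 360239 for CLK head, 359751 to 360263 for CLK testis and 359778 to 360567 for CYC testis. CLK testis (X 356051 to 356399) and CLK ovary (X 356180 to 356418) had peaks just outside that gene. The peaks at y were not checked against construct sequence either.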
